A study of Homo sapiens with 9 samples.

How the data were processed

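RNA was measured by sequencing in 9 libraries, 3 from each of 3 groups of cells labelled as MCF7, an established line derived from a human breast carcinoma. The groups were breast cancer stem cells (BCSCs), quiescent BCSCs (qBCSCs) and activated qBCSCs, all with the label CD44high/CD24low. The labels give all 3 groups the same 2 weeks of tumorsphere culture, with medium changed every 2 days. That medium held 20 ng/ml each of the growth factors EGF and bFGF and 10% serum replacement. Per the labels, qBCSCs were the cells that still held the membrane dye PKH26 after 2 weeks of tumorsphere culture and were collected by flow sorting. Dividing cells dilute this dye. Activated qBCSCs were sorted qBCSCs cultured for 20 h with 50 ng/ml exosomes isolated from the supernatant of MCF7 cells. Total RNA was extracted with TRIzol and made into libraries by standard Illumina protocols, per the labels' protocols.

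The authors deposited the values as FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, in a single table with a column per library. The submitters' processing notes name Bowtie2 2.2.9, TopHat2 2.1.1, Cuffdiff 2.2.1 and the mouse build mm9, with no role or order. The table's identifiers are human, with 58302 Ensembl gene IDs and 680 of another form. The human build and annotation release, the handling of strand and the treatment of fragments that map to several places are not given in the sources used here. No coordinates are therefore printed. Of 58982 genes, 38662 have no name in the table, and 37351 of these were named from a GENCODE-based table of gene names. A few names in the table have the form of dates and were kept with their IDs.

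Low FPKM values rise in steps, which give the relative depth of the libraries. Whole fragments were recovered for 12654 of the 24539 genes above 0 in at least 5 libraries. The search went up to 400 fragments, at a tolerance of 0.003 that widened with the number. Of these genes, 6828 had a single annotated transcript in GENCODE release 29. Among them 99.2% gave a depth within 0.1 M fragments of the most frequent value. For these genes the table thus behaves as whole fragments divided by length and depth. The estimated depths, in M (mega) fragments, were 46.8, 53.2 and 40.3 for BCSCs 1 to 3, 42.3, 36.2 and 53.4 for qBCSCs 1 to 3, and 46.9, 50.1 and 54.6 for activated qBCSCs 1 to 3. On these recovered fragments, libraries of a group differed by 3.4 to 5.22 times the variance of sampling noise, and libraries of different groups by 10.3 to 32.2 times. No library was therefore a repeat of another. The numbers served only for depth and noise, and no count model was fitted.

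Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 14395. The values were transformed as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 fitted group means to all 9 libraries with an intensity trend in the empirical Bayes step. Fold changes are on this scale, which understates the change of low genes. The 3 pairwise comparisons and an F test of any group difference were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. On simulated values with the means and spreads of these 14395 genes, 200 genes were changed between BCSCs and qBCSCs. The fit recovered 4% of the genes changed 1.2-fold, 70% at 1.5-fold, 98% at 2-fold and 98% at 4-fold, with 7 false calls. In the data 8482 to 11141 genes were called per comparison, which loosens the Benjamini-Hochberg cut. Recovery of small changes in the data may therefore be higher than these shares. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

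Before the data were examined, 27 gene lists, 4 sets of markers of other cell types, the alternatives and a rule for the genes named were fixed. The lists covered mitosis, DNA replication, quiescence, immediate early genes, stem cell markers, mesenchymal, epithelial, estrogen and luminal, and basal genes. Others covered hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, cholesterol synthesis, the unfolded protein and integrated stress responses, heat shock, p53 targets, interferon response and NF-kB. The last covered Wnt, Notch, Hedgehog, TGF-beta and BMP targets, autophagy and lysosome, exosomes, histones and the mitochondrial genome. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 81 tests, and again with an estimated correlation. For some lists the estimate was near or below 0.01 and p still rose, so these settings differ in more than the correlation. The rule named, per comparison, the 8 largest rises and 8 largest falls with adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap of libraries. Clone and locus names and duplicated symbols were passed over. It added up to 4 members with the smallest p of each list that passed, the genes CD44, CD24, MKI67, CDKN1A, CDKN1B, CCND1, MYC and ESR1, and the 8 genes with the largest opposite changes in the quiescence and activation comparisons.

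The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, equal FPKM sums, no intensity trend, robust empirical Bayes, only the 2 groups compared, a minimum fold of 2, the replicate number as a block, an estimated correlation for lists, and each library left out in turn. A fit to the genes named in the table was added after seeing the data. Replicate numbers are shared by the groups, but no label says what they mark. Deviations from the group means of same-numbered libraries were correlated across genes. For BCSCs against qBCSCs, the 3 correlations were 0.178, 0.15 and 0.192, all over 0.1. In the comparisons with activated qBCSCs they were not all over 0.1. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.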

Results

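The libraries fell into 3 groups of 3: BCSCs, qBCSCs and activated qBCSCs, all labelled as MCF7 and as CD44high/CD24low. The series compared gene expression among these groups. The estimated depth was 36.2 to 54.6 M (mega) fragments per library, and 13054 to 13945 genes reached 1 FPKM. Libraries of the same group correlated at r = 0.991 to 0.995 across the 14395 genes tested. The correlation was 0.885 to 0.895 between BCSCs and qBCSCs, 0.936 to 0.940 between BCSCs and activated qBCSCs, and 0.958 to 0.960 between qBCSCs and activated qBCSCs. The first principal component held 73.0% of the variance and placed activated qBCSCs between the other groups. A second, with 18.2%, set activated qBCSCs apart from both.

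The surface markers named in the label were measured as RNA. CD44 (ENSG00000026508), the hyaluronan receptor, stood at 524 ± 12.2 FPKM in BCSCs, 573 ± 25.1 in qBCSCs and 517 ± 19.2 in activated qBCSCs (mean ± SD, n = 3). Its differences did not pass (adjusted p = 0.076, 0.0569 and 0.793). The difference between activated qBCSCs and qBCSCs passed with quantile normalization (adjusted p = 0.00743), with equal FPKM sums (0.0247), and without qBCSCs replicate 3 (0.0376) or activated qBCSCs replicate 3 (0.0433), in a range of 0.00743 to 0.192 over the alternatives. That between qBCSCs and BCSCs passed without qBCSCs replicate 3 (adjusted p = 0.0443, range 0.0443 to 0.634), and that between activated qBCSCs and BCSCs with quantile normalization (0.0223, range 0.0223 to 0.980). CD24 (ENSG00000272398) was low throughout, at 2.69 ± 0.374, 1.82 ± 0.194 and 1.57 ± 0.111 FPKM. At these low levels it was called lower than in BCSCs in qBCSCs (log2 fold -0.385 ± 0.117 SE, adjusted p = 0.00981). The same held for activated qBCSCs (-0.513 ± 0.117 SE, adjusted p = 0.00217). Its difference between activated qBCSCs and qBCSCs did not pass (adjusted p = 0.366). ESR1, the estrogen receptor gene, was at most 0.548 FPKM in any library and was below the filter. The highest values of other luminal or epithelial genes in any library were 0.51 FPKM for GATA3, 0.336 for CDH1, 0.909 for KRT19 and 1.72 for EPCAM. The luminal transcription factor gene FOXA1 stood at 10.5 to 17.2 FPKM, the keratin genes KRT8 and KRT18 at 1012 to 1862 and 314 to 548, and the mesenchymal filament gene VIM at 82.5 to 207. MTAP, a gene chosen after these levels were seen, stood at 16.8 to 27.1 FPKM.

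The comparison of qBCSCs with BCSCs set the sorted, dye-retaining cells against BCSCs. The labels do not say whether BCSCs were labelled with dye and sorted alike. For every result of this comparison, dye retention therefore cannot be told apart from labelling and sorting. Target genes of p53 rose together: all 25 tested members were higher in qBCSCs, with a median log2 fold of 2.33 (interquartile range 1.69 to 3.18). CDKN1A (ENSG00000124762), which encodes the cell cycle inhibitor p21, rose from 125 ± 6.12 FPKM in BCSCs to 2390 ± 164 in qBCSCs (log2 fold 4.25 ± 0.07 SE, adjusted p = 2.79e-12). GDF15 (ENSG00000130513), a stress-induced cytokine, rose from 139 ± 5.1 to 4791 ± 141 FPKM, and DDB2, a DNA repair gene, from 48.3 ± 0.967 to 475 ± 39.3. TP53INP1 (ENSG00000164938) rose from 0.329 ± 0.0465 to 61.4 ± 2.5 FPKM. The list passed at an adjusted p of 2.3e-11, and of 0.0162 with an estimated correlation.

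Genes of ribosome production were lower in qBCSCs with the preset correlation only. In the ribosome biogenesis list, 25 of 30 members were lower and 1 higher, with a median log2 fold of -1.19 (adjusted p = 8.15e-08, and 0.0577 with an estimated correlation). UTP20, a component of the machinery that processes ribosomal RNA, fell from 51.7 ± 3.77 to 5.51 ± 0.077 FPKM, and BOP1 from 258 ± 2.68 to 47.9 ± 5.07. Of 33 ribosomal protein genes, 30 were lower and none higher, with a median of -0.83 (adjusted p = 3.76e-07, and 0.526 with an estimated correlation). RPL3 fell from 2301 ± 113 to 619 ± 52.8 FPKM. Fragments of ribosomal protein genes can be shared with processed pseudogenes, so single values of that family are uncertain. MYC (ENSG00000136997), a transcription factor gene that promotes growth, fell from 242 ± 21.9 to 55.5 ± 5.02 FPKM (log2 fold -2.11 ± 0.08 SE, adjusted p = 7.54e-10).

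The interferon, exosome, autophagy and lysosome, and cholesterol lists rose in qBCSCs with the preset correlation only. Interferon response genes were higher in 20 of 23 members and lower in 1 (median 1.13, adjusted p = 0.000156, and 0.0664 with an estimated correlation). IFI6 rose from 32.3 ± 1.49 to 179 ± 8.71 FPKM, and the antiviral regulator IRF7 from 4.06 ± 0.738 to 54.3 ± 6.39. In the exosome list 17 of 20 members rose and 1 fell (median 0.90, adjusted p = 0.000269, and 0.0577 with an estimated correlation). The vesicle membrane protein gene CD63 rose from 719 ± 52.5 to 3281 ± 154 FPKM. Autophagy and lysosome genes rose in 22 of 29 members and fell in 5 (median 0.79, adjusted p = 0.00152, and 0.138 with an estimated correlation), with CTSB, a lysosomal protease gene, rising from 203 ± 0.982 to 615 ± 21.5. Cholesterol synthesis and uptake genes rose in 19 of 27 and fell in 2 (median 0.65, adjusted p = 0.0021, and 0.302 with an estimated correlation). LDLR, the gene of the low-density lipoprotein receptor, rose from 38.8 ± 2.25 to 259 ± 44.4 FPKM.

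Immediate early genes, which respond to growth factors and to cell handling, rose in 21 of 28 members and fell in 7. Their median log2 fold was 1.02 (adjusted p = 0.00635, and 0.409 with an estimated correlation). EGR1 rose from 3.91 ± 0.464 to 90.7 ± 7.81 FPKM and FOS from 25.4 ± 1.15 to 180 ± 21.4, whereas MYC, also on this list, fell. Histone genes rose in 9 of 12 members, or 8 adjusted over the list alone, and none fell (adjusted p = 0.00973, and 0.425 with an estimated correlation). HIST1H2BD rose from 8.97 ± 0.674 to 111 ± 21.9 FPKM. Histone genes are near-identical copies and most of their mRNAs lack a poly(A) tail, so these values are uncertain. Genes of the unfolded protein and integrated stress responses were lower in 16 of 24 members and higher in 6 (median -0.64, adjusted p = 0.0385, and 0.337 with an estimated correlation). HSP90B1, an endoplasmic reticulum chaperone gene, fell from 1472 ± 52.5 to 474 ± 23.3 FPKM, while SESN2 rose from 11.2 ± 0.586 to 37.2 ± 2.34. TGF-beta and BMP targets were lower in 10 of 14 and higher in 4 (median -1.05, adjusted p = 0.0441, and 0.343 with an estimated correlation). PMEPA1 fell from 43.2 ± 2.58 to 10.5 ± 0.691 FPKM. The call of this list was also lost with the replicate block (adjusted p = 0.0539), median-ratio rescaling (0.0619), only the 2 groups compared (0.0679), the genes named in the table (0.0528), and without qBCSCs replicate 3 (0.0545) or activated qBCSCs replicate 1 (0.0553) or 2 (0.0587), in a range of 0.00205 to 0.343. The call of the stress response list was also lost with a mean of at least 5 FPKM (adjusted p = 0.0516), only the 2 groups compared (0.0549) and without qBCSCs replicate 3 (0.0545), in a range of 0.00167 to 0.337.

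The largest rises in qBCSCs were NECTIN4, TP53INP1, MIR3189, GDF15, GRIN2C, TXNIP, HM13-AS1 and PI3. NECTIN4 (ENSG00000143217), a cell adhesion gene, rose from 0.236 ± 0.0425 to 104 ± 2.88 FPKM (log2 fold 6.41 ± 0.07 SE, adjusted p = 1.83e-13). TXNIP, which encodes an inhibitor of thioredoxin, rose from 18.0 ± 1.8 to 480.2 ± 34.3. MIR3189 lies within GDF15 and HM13-AS1 is an antisense gene, so their values cannot be separated from the overlapping genes. The largest falls were CDH5, KRT7, KRT17, MT1X, PSG4, FSTL3, ALPP and FUOM. KRT7, a keratin gene of simple epithelia, fell from 3772 ± 111 to 114 ± 5.42 FPKM, and KRT17, a basal keratin gene, from 318 ± 5.59 to 11.2 ± 1.23. CDH5, the gene of a cadherin best known from endothelium, fell from 53.9 ± 0.883 to 0.309 ± 0.0709 FPKM. Among the genes on this list, MT1X, PSG4 and ALPP have close paralogs and are uncertain. In all, 5944 genes were higher and 5197 lower in qBCSCs, and 2034 and 1909 of them changed at least 2-fold. Together the calls made up 77.4% of the genes tested, which is the background for counts within a list. With median-ratio rescaling, 5483 were higher and 5594 lower, so which direction held more genes depended on the scaling. The libraries of the groups did not overlap for 78.6% of genes, where chance gives 10%.

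**Figure D1:**
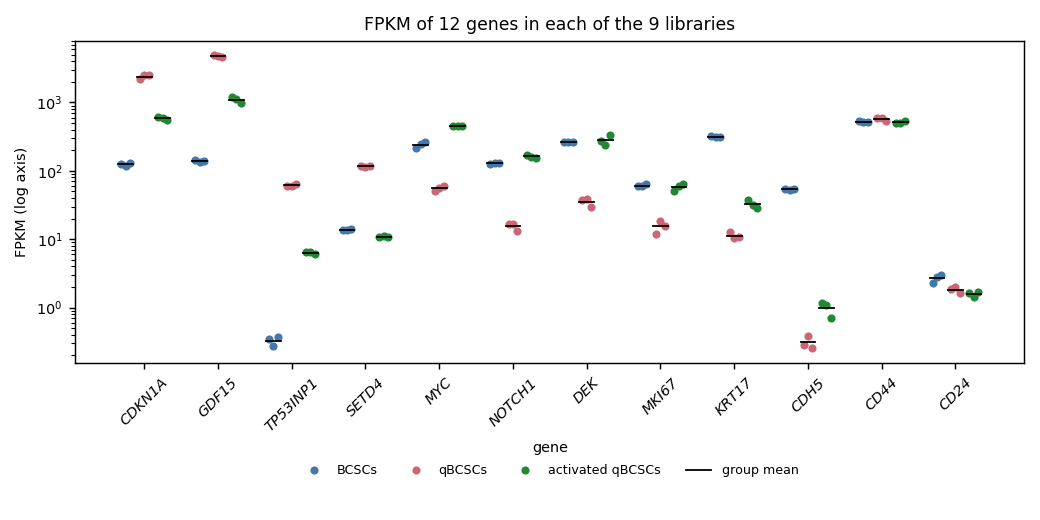
FPKM of 12 genes (log axis) in each of the 9 libraries, with a point per library and a bar at the mean of the 3 libraries of a group. CDKN1A, GDF15, TP53INP1 and SETD4 were highest in qBCSCs, MYC, NOTCH1, DEK and MKI67 were lowest there, and KRT17 and CDH5 were highest in BCSCs.

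MKI67 fell in qBCSCs, whereas the mitosis list did not pass. MKI67 (ENSG00000148773), which encodes the proliferation antigen Ki-67, stood at 60.9 ± 2.39 FPKM in BCSCs and 15.4 ± 3.23 in qBCSCs (log2 fold -1.93 ± 0.13 SE, adjusted p = 5.68e-08). Its longest annotated transcript is 12.7 kb. Within the mitosis list fold and transcript length had a Spearman rho of -0.479, or -0.429 without MKI67, across genes, which are not independent replicates. Of the 33 mitotic genes, however, 16 were higher and 9 lower, with a median of 0.14 (adjusted p = 0.337). Among all 14395 genes tested, 5944 were higher and 5197 lower, so counts of this kind say little by themselves. Genes chosen after their values were seen include CKS2, which rose from 131 to 594 FPKM, and TOP2A, at 269 and 273. DNA replication genes were lower in 20 of 38 and higher in 10 (median -0.23, adjusted p = 0.0751). This list passed with no filter on low values (adjusted p = 0.00414) and with quantile normalization (0.0366), in a range of 0.00414 to 0.337 over the alternatives. In the quiescence list, 19 of 32 members were higher and 10 lower (median 0.48, adjusted p = 0.124), and it passed with no filter (0.0132, range 0.0132 to 0.526). The cyclin D1 gene CCND1 fell from 201 ± 6.84 to 112 ± 7.54 FPKM, and CDKN1B, which encodes the cell cycle inhibitor p27, fell from 117 ± 2.99 to 67.0 ± 0.812 (adjusted p = 2.16e-07 and 1.2e-07).

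The comparison of activated qBCSCs with qBCSCs addressed the response to exosomes. No group of qBCSCs kept for the same 20 h without exosomes was analysed here. Ribosome biogenesis genes rose in all 30 members, with a median log2 fold of 1.14 (adjusted p = 2.13e-13, and 0.0199 with an estimated correlation). DKC1, which encodes the pseudouridine synthase dyskerin, rose from 90.3 ± 0.224 to 233 ± 8.63 FPKM (adjusted p = 8.46e-09). Ribosomal protein genes were higher in 30 of 33 members and lower in none (median 0.47, adjusted p = 8.73e-07, and 0.526 with an estimated correlation). RPL4 rose from 615 ± 53.2 to 1103 ± 0.52 FPKM. MYC rose to 456 ± 2.94 FPKM (log2 fold 3.02 ± 0.08 SE, adjusted p = 5.44e-10), and MKI67 to 58.3 ± 6.52 (log2 fold 1.87 ± 0.13 SE, adjusted p = 3.36e-07).

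Genes of the p53 list fell in 24 of 25 members on activation and 1 rose, with a median log2 fold of -1.26 (adjusted p = 5.7e-13, and 0.0162 with an estimated correlation). CDKN1A fell from 2390 ± 164 to 591 ± 28.8 FPKM and GADD45A, a DNA damage response gene, from 281 ± 24.4 to 47.1 ± 4.64. Autophagy and lysosome genes were lower in 19 of 29 members, or 20 adjusted over the list alone, and higher in 2. Their median was -0.32 (adjusted p = 0.000439, and 0.101 with an estimated correlation). NEU1, a lysosomal sialidase gene, fell from 75.9 ± 4.08 to 41.6 ± 2.12 FPKM. Immediate early genes were lower in 16 of 28 and higher in 5 (median -0.45, adjusted p = 0.024, and 0.471 with an estimated correlation). ATF3 fell from 51.2 ± 2.06 to 23.2 ± 1.64 FPKM, whereas TRIB1 rose from 18.0 ± 0.914 to 44.9 ± 1.03.

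The largest rises on activation were LHCGR, MAP2K6, LGALS7B, NOTCH1, URGCP, MYC, DCN and DEK. NOTCH1 (ENSG00000148400), a receptor gene of cell fate signalling, rose from 15.6 ± 2 to 163 ± 7.68 FPKM (log2 fold 3.31 ± 0.08 SE, adjusted p = 4.83e-10). LHCGR, the gene of a gonadotropin receptor, rose from 1.32 ± 0.248 to 35.4 ± 0.12 FPKM. DEK (ENSG00000124795), which encodes a chromatin protein, rose from 35.1 ± 5.11 to 281 ± 48 FPKM, beside 266 ± 3.97 in BCSCs. LGALS7B has a near-identical copy and is uncertain. The largest falls were SETD4, BMP2, TP53INP1, BTBD19, MIR3189, NGFR, ID2 and GADD45A. SETD4 (ENSG00000185917), a methyltransferase gene linked to cell quiescence, stood at 13.9 ± 0.298 FPKM in BCSCs, 116 ± 0.778 in qBCSCs and 10.9 ± 0.324 in activated qBCSCs. Its log2 fold on activation was -3.30 ± 0.06 SE (adjusted p = 6.17e-11). BTBD19 varied widely in qBCSCs, at 38.4 ± 16.4 FPKM. In all, 4171 genes were higher and 4311 lower, and 666 and 553 of them changed at least 2-fold. Together the calls made up 58.9% of the genes tested. With median-ratio rescaling, 4222 were higher and 4194 lower. For 61.7% of genes the libraries of the groups did not overlap, against 10% by chance.

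Other lists of the activation comparison did not pass as fitted but did under an alternative. TGF-beta and BMP targets were lower in 8 of 14 and higher in 4 (median -0.34, adjusted p = 0.0757). They passed with no filter on low values (adjusted p = 0.0167), with a mean of at least 5 FPKM (0.0262) and without activated qBCSCs replicate 1 (0.04996), in a range of 0.0167 to 0.419. Cholesterol genes were lower in 12 of 27 and higher in 4 (median -0.15, adjusted p = 0.0924), and passed with no filter (0.0123) and without qBCSCs replicate 1 (0.0377), in a range of 0.0123 to 0.522. Exosome genes (adjusted p = 0.0812, range 0.00826 to 0.302) and unfolded protein and integrated stress response genes (0.16, range 0.0365 to 0.511) passed with no filter only.

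Some members of the lists that passed moved against their list and are named after their values were seen. In qBCSCs against BCSCs these were POLR1C among ribosome biogenesis genes, DDX60 among interferon genes, STAM in the exosome list, and FDPS and FASN among cholesterol genes. GABARAPL1, ULK1, ATG7, CTSA and TFEB did so in the autophagy and lysosome list, and SERPINE1, ID2, BAMBI and BMP4 among TGF-beta and BMP targets. DUSP1, DUSP4, MYC, KLF6, KLF10, NR4A3 and CYR61 fell among immediate early genes, and ATF3, SESN2, DNAJB9, CALR, PPP1R15A and CEBPB rose among stress response genes. On activation these were PERP among p53 targets, ATG5 and ATG7 in the autophagy and lysosome list, and DUSP4, MYC, KLF6, TRIB1 and SPRY2 among immediate early genes. In activated qBCSCs against BCSCs these were SERPINE1, SESN2, CEBPB, IFI35, STAT1, STAM, MVD and FDPS, from the TGF-beta and BMP, stress response, interferon, exosome and cholesterol lists, and ATF3, DUSP1, KLF6, KLF10, NR4A3 and CYR61 among immediate early genes.

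**Figure D2:**
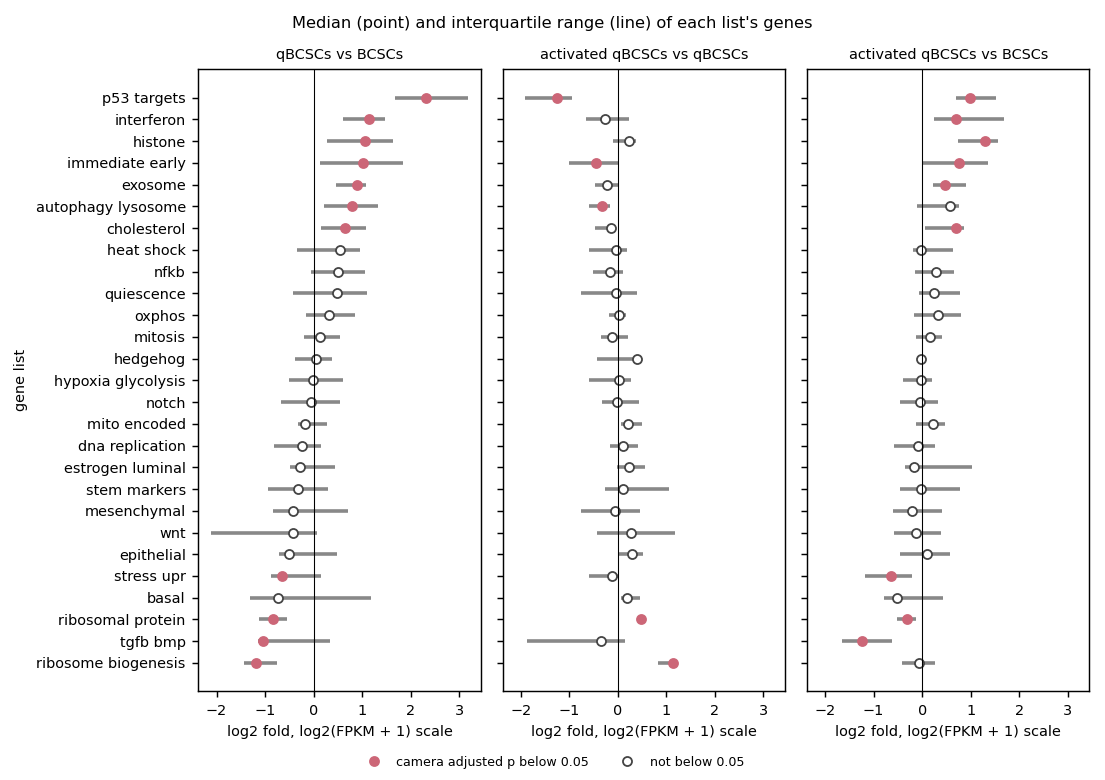
Median log2 fold (points) and interquartile range (lines) of the tested genes of each of 27 lists in the 3 comparisons, on the log2(FPKM + 1) scale. Filled points mark lists with a camera adjusted p below 0.05 at the preset correlation: 11, 5 and 9 lists from left to right, of which p53 targets, ribosomal proteins and immediate early genes passed in all 3, though only p53 targets did so in all 3 with an estimated correlation.

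The comparison of activated qBCSCs with BCSCs addressed how far the activated cells had returned. The p53 list stayed higher in 23 of 25 members and was lower in none (median 0.98, adjusted p = 2.99e-08, and 0.0199 with an estimated correlation). GDF15 stood at 1100 ± 107 FPKM against 139 ± 5.1, and CDKN1A at 591 ± 28.8 against 125 ± 6.12. Ribosome biogenesis genes were higher in 10 of 30 and lower in 12 (median -0.06, adjusted p = 0.544). Ribosomal protein genes were lower in 18 of 33 and higher in none (median -0.30, adjusted p = 0.000453, and 0.656 with an estimated correlation). For MKI67 the log2 fold was -0.07 ± 0.13 SE (adjusted p = 0.661). MYC was higher in activated qBCSCs than in BCSCs, at 456 ± 2.94 against 242 ± 21.9 FPKM (log2 fold 0.91 ± 0.08 SE, adjusted p = 1.56e-06).

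TGF-beta and BMP targets were lower in 11 of 14 members and higher in 1 (median -1.24, adjusted p = 0.000153, and 0.097 with an estimated correlation). ID1, ID2 and ID3, which encode inhibitors of differentiation factors, all fell; ID1 stood at 28.1 ± 1.49 FPKM against 321 ± 3.8 in BCSCs (adjusted p = 6.32e-11). Unfolded protein and integrated stress response genes were lower in 19 of 24 and higher in 2 (median -0.64, adjusted p = 2.47e-05, and 0.0701 with an estimated correlation). HSPA5, the main chaperone gene of the endoplasmic reticulum, stood at 350.2 ± 8.34 against 877 ± 10.7 FPKM. Interferon genes were higher in 16 of 23, or 17 adjusted over the list alone, and lower in 2 (median 0.70, adjusted p = 0.000265, and 0.0693 with an estimated correlation). OASL, an antiviral gene, stood at 28.9 ± 1.4 against 3.49 ± 0.676 FPKM. Exosome genes were higher in 16 of 20, or 17 adjusted over the list alone, and lower in 1 (median 0.46, adjusted p = 0.000478, and 0.0616 with an estimated correlation). RAB27B, which encodes a GTPase of vesicle release, stood at 56.7 ± 6.37 against 13.7 ± 0.381 FPKM.

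Cholesterol genes were higher in 17 of 27 members and lower in 2 (median 0.70, adjusted p = 0.00635, and 0.337 with an estimated correlation), with PCSK9 at 40.8 ± 1.79 against 10.7 ± 0.928 FPKM. Autophagy and lysosome genes were higher in 18 of 29 and lower in 6 (median 0.57, adjusted p = 0.0518) and passed in 6 of 20 alternatives, in a range of 0.000734 to 0.337. Among these were the fits without BCSCs replicate 2 (adjusted p = 0.0439), qBCSCs replicate 1 (0.0492) or activated qBCSCs replicate 3 (0.0363). Histone genes were higher in 10 of 12, or 11 adjusted over the list alone (median 1.30, adjusted p = 0.000265, and 0.302 with an estimated correlation). Immediate early genes were higher in 19 of 28, or 20 adjusted over the list alone, and lower in 6 (median 0.76, adjusted p = 0.00973, and 0.425 with an estimated correlation). The largest rises against BCSCs were PI3, AKR1C3, COL17A1, NECTIN4, SERPINE2, LGALS7B, TXNIP and SCAT8. PI3, the gene of the elastase inhibitor elafin, rose from 0.655 ± 0.181 to 128 ± 4.03 FPKM (log2 fold 6.29 ± 0.09 SE, adjusted p = 1.69e-12), and SERPINE2 from 51.7 ± 0.777 to 842 ± 21.8. The largest falls were PSG4, ALPI, CDH5, ANO2, LAMA1, OLR1, CPA4 and MT1X. LAMA1, a basement membrane laminin gene, fell from 41.9 ± 3.6 to 1.28 ± 0.142 FPKM. In all, 5222 genes were higher and 4221 lower than in BCSCs, and 991 and 1034 of them changed at least 2-fold. Together the calls made up 65.6% of the genes tested. Median-ratio rescaling gave 4653 higher and 4729 lower. The libraries of the groups did not overlap for 72.0% of genes. The F test called 12331 genes. Of the 27 lists, 16 passed in none of the comparisons as fitted, and some of these passed under an alternative.

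Most changes of qBCSCs were partly undone in activated qBCSCs. TP53INP1, LHCGR, MIR3189, NECTIN4, GRIN2C, BTBD19, HM13-AS1 and GDF15 had the largest opposite changes. LHCGR stood at 39.1 ± 0.385 FPKM in BCSCs, 1.32 ± 0.248 in qBCSCs and 35.4 ± 0.12 in activated qBCSCs, whereas NECTIN4 fell only from 104 ± 2.88 to 20.9 ± 0.507, against 0.236 ± 0.0425 in BCSCs. Of the 3943 genes changed at least 2-fold in qBCSCs, 2965 (75.2%) were called in the opposite direction on activation and 126 in the same direction. A median of 58.2% of the change was left in activated qBCSCs (interquartile range 37.2% to 79.3%), and 3438 of these genes (87.2%) still differed from BCSCs in the same direction.

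Over all tested genes, 6480 were called in opposite directions, 3459 up then down and 3021 down then up. Independent lists of the same sizes would share 1780 and 1506. Calls in the same direction numbered 440 up and 313 down, against 1722 and 1556. The qBCSC libraries enter both comparisons and are too few to be split, so part of this excess of opposite calls may come from sharing them. The log2 folds of the comparisons correlated at r = -0.674 across genes, which are not independent replicates. With the qBCSC libraries shared in this way, 100 simulations of unchanged groups, in which libraries varied independently and no pairing by replicate number was kept, gave a mean r of -0.501 and at most 1 gene called in opposite directions. The covariance was -0.397, against -0.0103 simulated, a difference of -0.387. Groups without a true change give few calls of any kind, so the simulated count is no measure for the 6480 opposite calls. A shift common to all qBCSC libraries would enter both comparisons with opposite sign, and it was not simulated.

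**Figure D3:**
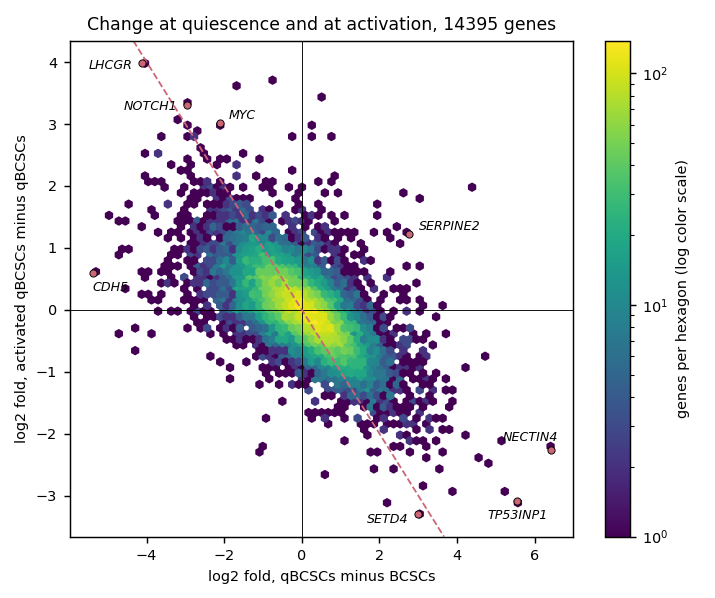
Log2 fold of qBCSCs minus BCSCs (horizontal) against activated qBCSCs minus qBCSCs (vertical), on the log2(FPKM + 1) scale, for 14395 genes, colored by the number of genes per hexagon on a log scale. The dashed line marks a full return to the BCSC level; LHCGR lies near it, NECTIN4 lies short of it, and SERPINE2 rose in both steps.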

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

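The fit to the genes named in the table was added after seeing the data, and the other alternatives were planned. Of the counts recomputed, 122 stayed within 1.5 times and 5 fell further. A minimum fold of 2, which by construction calls fewer genes, left 3943 genes for qBCSCs against BCSCs, 1219 for activated qBCSCs against qBCSCs, 2025 for activated qBCSCs against BCSCs, and 862 genes with opposite calls. With an estimated inter-gene correlation, 4 rather than 25 of 81 list tests passed. The estimate was 0.709 for ribosomal proteins, but 0.0112 for p53 targets and -0.0422 for exosomes, near or below the preset 0.01. In qBCSCs against BCSCs the camera p of p53 targets still rose from 8.52e-13 to 0.000399. That of exosomes rose from 4.32e-05 to 0.00427. Calls lost in this setting therefore cannot be put down to inter-gene correlation alone. Lists that had not passed did so in 23 cases over the alternatives, 10 of them with no filter on low values. Leaving out 1 library gave 10585 to 11160, 7634 to 8461 and 8676 to 9863 genes in these comparisons, 11834 to 12403 for any group difference, 5900 to 6378 opposite calls and 23 to 28 list tests. The fit to the genes named in the table called 9402, 7538 and 8117.

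With the replicate number as a block, 11313, 8797 and 9727 genes were called, 12547 for any group difference, 6702 in opposite directions and 24 list tests. The block ended the call of the TGF-beta and BMP list in qBCSCs against BCSCs and changed no other list or named gene call. Of the 9 pairs of same-numbered libraries, 5 had a correlation of deviations over 0.1. In both other groups at once, 4 of 9 libraries correlated best with their own number. Between BCSCs and qBCSCs, same-numbered pairs had 0.178, 0.15 and 0.192, against at most 0.0731 for the other pairs. These values are a hint from the data and not from the design.

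Results that changed direction were far from the threshold before and after, and the cause was not tested. For MKI67 in activated qBCSCs against BCSCs, the log2 fold became 0.025 without activated qBCSCs replicate 1, in a range of -0.13 to 0.025 over the libraries left out. For the lists, the adjusted p after the change was as follows. Estrogen and luminal genes, activated qBCSCs against BCSCs, had 0.954 and 0.907 with pseudocounts of 0.1 and 5, 0.463 with a mean of at least 5 FPKM, 0.887 with only the 2 groups compared, 0.94 with the block, and 0.896 and 0.987 without qBCSCs replicate 1 or 2, in a range of 0.854 to 1.00 over the libraries left out. In activated qBCSCs against qBCSCs, oxidative phosphorylation had 0.96 with a mean of at least 5 FPKM, 0.937 with equal sums, 0.998 with only the 2 groups, and 0.924 and 0.83 without qBCSCs replicate 2 or 3, in a range of 0.621 to 0.987. Hypoxia and Hedgehog genes had 0.917 and 0.917 with no filter, and Notch genes 0.997 with a mean of at least 5 FPKM. Hedgehog genes in qBCSCs against BCSCs had 0.957 with no filter and 0.92 without qBCSCs replicate 1, in a range of 0.734 to 0.92. Epithelial genes in activated qBCSCs against BCSCs had 0.734 with a mean of at least 5 FPKM. Depth limits what can be said of genes near 1 FPKM, and simulated 1.2-fold changes were recovered in 4% of cases.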

Other observations

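The tests on handling, normalization, cycling cells and other splits were chosen after their results were seen; those on MTAP and transcript length were set before the values they measure were looked at, though after the patterns. Markers of other cell types were fixed before the data were examined. Of 14 leukocyte markers, 4 reached 1 FPKM in a library, as did 6 of 11 fibroblast, 3 of 9 endothelial and 2 of 7 erythroid markers. SRGN, a proteoglycan gene, had the highest level, with 144, 528 and 304 FPKM in BCSCs, qBCSCs and activated qBCSCs, whereas PTPRC reached at most 0.159 FPKM. COL1A1 stood at 71.4, 104 and 40.4 FPKM while COL1A2 reached at most 0.0221. The endothelial marker CDH5 fell from 53.9 FPKM in BCSCs to 0.309 in qBCSCs. The fibroblast marker DCN rose from 1.05 FPKM in qBCSCs to 15.4 in activated qBCSCs. Both are among the largest changes named above, and no cell type was called from these markers.

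Among the 16 lists that passed in no comparison as fitted, the smallest camera adjusted p was 0.0544 for quiescence, 0.0751 for DNA replication, 0.124 for estrogen and luminal genes, 0.125 for epithelial genes and 0.128 for oxidative phosphorylation. It was 0.138 for Wnt, 0.174 for NF-kB, 0.318 for the mitochondrial genome, 0.319 for mitosis, 0.33 for stem cell markers and 0.33 for basal genes. For heat shock it was 0.333, for mesenchymal genes 0.439, for hypoxia and glycolysis 0.579, for Hedgehog 0.644 and for Notch 0.715. With no filter on low values, DNA replication (adjusted p = 0.00414, range 0.00414 to 0.337 over the alternatives) and quiescence (0.0132, range 0.0132 to 0.526) passed in qBCSCs against BCSCs. Quiescence (0.00266), mitosis (0.0417, range 0.0417 to 0.738) and oxidative phosphorylation (0.0265, range 0.0265 to 0.656) did so in activated qBCSCs against BCSCs. With quantile normalization, DNA replication (0.0366) passed in the first of these comparisons and quiescence (0.042) in the second. Quiescence genes in activated qBCSCs against BCSCs passed without BCSCs replicate 2 (adjusted p = 0.0471) or 3 (0.0365), in a range of 0.00266 to 0.486 over the alternatives, and genes of the mitochondrial genome in activated qBCSCs against qBCSCs passed without qBCSCs replicate 1 (0.035, range 0.035 to 0.832). Median, mean and test differed in sign in 8 of 81 list tests, 0 of which passed. Single stem cell genes moved apart: BMI1 stood at 27.6, 139 and 44.1 FPKM in BCSCs, qBCSCs and activated qBCSCs, NOTCH1 at 128, 15.6 and 163, and CXCR4 at 32.2, 29.7 and 91.7, genes chosen after their values were seen.

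Libraries labelled as MCF7, a line known for its luminal genes, held next to none of ESR1 (at most 0.548 FPKM), GATA3 (0.51), PGR (0.0864) or CDH1 (0.336), although the luminal genes FOXA1 (10.5 to 17.2 FPKM) and KRT18 (314 to 548) were present and 20 of 29 estrogen and luminal genes passed the filter. MCF7 is known to lack MTAP and the neighbouring CDKN2A through a homozygous deletion. MTAP was at least 16.8 FPKM in all 9 libraries, and CDKN2A, which the test did not set in advance, 410 to 954. The values argue against a selection of CD44high/CD24low cells within MCF7, which cannot restore a deleted gene, and a candidate explanation is that the cells were of a line other than MCF7. Which line was not examined, and a mixture of lines was not tested.

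The rise of p53 targets in qBCSCs was weighed against normalization and handling. Under 3 rescalings the median log2 fold of the list was at least 2.25, against 2.33 as deposited. The rise thus did not depend on the choice among these scalings. The median over all genes was only -0.0047 to 0.0636 in these fits. Shifts that small could not remove the rise, so the rescalings could not decide on normalization as a cause. Handling may contribute: immediate early genes had a median of 1.02 (camera adjusted p = 0.00635, and 0.409 with an estimated correlation), and heat shock genes, with a median of 0.55, did not pass (0.333). The labels describe dye labelling and sorting for qBCSCs and do not say whether BCSCs were handled alike, so handling cannot be told apart from quiescence here. Quiescence itself, which the design names, stays open and untested.

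MKI67 fell in qBCSCs by 1.93 on the log2 scale while the other 32 mitotic genes had a median of 0.16 (interquartile range -0.09 to 0.56). If a lower share of cycling cells lowered mitotic genes alike, a premise not tested here, the others would fall with MKI67. Only 10 of the 32 had a fold below 0. MKI67 lay -2.09 from their median, more than the interquartile range of 0.652. That gap restates the pattern that prompted the test, since MKI67 had the lowest fold of the list. On that premise only, the values of the other members argue against fewer cycling cells as the whole cause of the MKI67 fall. Other genes did fall, among them BUB1B (-0.99), ANLN (-0.73) and CCNB1 (-0.64) of the mitosis list and 20 of 38 DNA replication genes, such as PCNA (-2.14), but 10 of the 38 rose, such as ORC6 (1.00), and that list did not pass (adjusted p = 0.0751, and 0.337 with an estimated correlation); these genes were named after their values were seen. The length trend of all genes is argued against as the whole cause, since MKI67, with a transcript of 12.7 kb in GENCODE release 29, still lay -1.92 from the others after it was subtracted. Spearman rho was -0.0747 over all genes, -0.479 within the list and -0.429 within the list without MKI67. A steeper trend within the list stays open. MKI67 lay -1.32 from a line through the other members, at -1.93 ± 0.13 SE against a lower 95% prediction bound of -1.86. It was thus below the bound, which the rule set before these values were looked at counted against this trend. The margin was smaller than the SE, however, and was treated as undecided, a condition that rule did not hold. The line was also drawn beyond the longest other transcript of 10.9 kb.

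Other splits of the libraries were fitted in the same way. For each pairwise comparison 1 of 10 splits, the real one, gave as many calls (11141, 8482 and 9443), with 0 genes at most in the other splits, whichever same-numbered libraries they parted; 10 splits are too few for a share under 0.05. For any group difference, 1 of 100 splits drawn, the real one, reached 12331 genes and the highest other gave 6588. This excludes chance only for how libraries were assigned to groups: if the libraries of a group share a culture, a chance difference between cultures is not excluded.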
